A study of Mus musculus with 4 samples.

How the data were processed

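CUT&Tag libraries of H3K9me3 and of control IgG were made from 100000 sorted microglia per sample with 14 cycles of PCR, per the labels' protocols. There were 4 groups of 1 library. The submitters' processing notes name CASAVA 1.4, Bowtie2 2, FastQC and the genome build mm9, without role or order. The peak caller, its settings, the use of the IgG libraries, the rule that put a region in a list and the annotation tool are not given in the sources used here.

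The authors' deposited lists hold 1 row per region for the comparison of KO with control, with 3488 regions in the list of increases and 1944 in that of decreases. Per the file headers, each row gives the position, the width, a peak score, an annotation class, the gene with the nearest transcription start and the distance to it. The score is the authors' own value for the peak. Its scale is not stated, and it was used only to describe and rank regions. The region names are numbered up to 6359, and 927 numbers are in neither list and were not analysed here. Because neither counts, fold changes nor p-values are given, the depth per library is unknown, and its effect on which regions were called cannot be measured. A deeper library lets weaker regions pass a threshold, so unequal depth alone can make the lists unequal in length.

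The build was checked through gene positions. Of 4741 gene symbols, 3356 matched a symbol and 43 a synonym in a RefSeq gene table of GRCm38.p6, and 1342 had no match. Of 3851 regions with a matched symbol, the transcript given for 3842 (99.8%) overlapped the GRCm38 gene of that name. Coordinates were therefore read as GRCm38, the assembly that followed mm9, and none was converted. The check covers the transcripts given in the rows and not the regions themselves. Regions placed on mm9 but annotated with GRCm38 genes would pass it, so the build of the regions stays uncertain. In 7 regions of 3 genes a date stood in place of the symbol, and the symbol was taken from the transcript name in the same row. Of 2062 regions inside an intron or exon of a named gene, 1170 (56.7%) had the start of another gene nearest. Genes were therefore also counted by the gene that holds the region.

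The design chosen before the data were examined made no test between genotypes, since each had 1 H3K9me3 library. It counted regions per list, annotation class, chromosome and gene set, with exact Clopper-Pearson 95% intervals. Class and chromosome shares were set beside 10000 draws of regions from both lists together, and shares of gene sets with at least 5 regions beside 10000 random sets of as many regions matched on 5 classes of width. Genes in both lists and directions of neighbours within 100 kb were set beside shuffled directions. The 14 gene lists and 18 gene families were written before the data were examined. The design foresaw a fold change per region, and the peak score took its place.

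The named genes were, by a rule set beforehand, the 10 regions with the highest score in each list, 1 per gene; the 5 genes with most regions in each list; up to 4 genes with the highest score from each gene set, over both lists; and Arid1a, Prg3, Prg2, Lrp6 and Cx3cr1 whatever their values. Predicted genes and RIKEN clones were counted but replaced in the text by the next gene with a name. Some genes that the rule selects are not reported here. Further members of sets, genes on X, genes of the 5' UTR class, the genes given as examples of both directions and the highest-scoring predicted genes were added after their values were seen.

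After the lists were examined, regions were also placed at random 1000 times on the same chromosomes, and overlaps with genes extended by 10 kb were counted. The placement ignores assembly gaps and mappability. Alternatives were a score at least 1 above the smallest, merging of regions within 10 kb, autosomes alone, each gene counted once, regions inside a gene or promoter, no width matching, neighbours within 10 kb or 1 Mb, the part of each list at or above its median score, the gene that holds the region, leaving out regions that scored above every lower region, matching of random sets also on X, the testis and X-linked set without Slx4ip, and gene bodies without flanks. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Both procedures were tested on simulated data. Sets of 40 regions whose share higher was raised by 25 points fell outside the random range in 99% of 200 runs and unchanged sets in 4%. Smaller sets were not simulated, although most gene sets with a percentile held fewer than 40 regions and would show such a rise less often. With 20 regions moved to zinc finger genes, the placement found them in 92.5% of 40 runs, and in 0% with none moved.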

Results

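H3K9me3, a histone mark of silent chromatin, was profiled in microglia, the resident macrophages of the brain, sorted from the telencephalon of mouse embryos. The labels give embryonic day 14, and the protocol a slightly later point. Control embryos carried floxed Arid1a. In knockout (KO) embryos Arid1a was targeted for loss by Cre driven by Cx3cr1, a gene expressed in microglia, in the cells that express Cre. Arid1a encodes a DNA-binding subunit of the SWI/SNF chromatin remodelling complex. The assay was CUT&Tag, in which an antibody directs a transposase to cut and tag the DNA at marked nucleosomes. There were 4 libraries, 1 each of H3K9me3 and of control IgG per genotype. The authors' lists of regions with more or less H3K9me3 in KO than in control are described here. They give neither read counts nor a value per library, so the depth is unknown and no difference has a replicate check. Whether the IgG libraries entered the scores or the choice of regions is not stated. Intervals in brackets are exact 95% binomial intervals that cover counting error only, and percentiles describe this pair of H3K9me3 libraries.

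The first question was how H3K9me3 differed in microglia of KO embryos. More regions were listed as higher in KO than as lower. The higher list held 3488 regions nearest to 3188 genes and the lower list 1944 regions nearest to 1846 genes, so that 64.2% (62.9 to 65.5) of the 5432 regions were higher. Among genes with a name, the claudin gene Cldn34d and Kctd16 had some of the highest scores in the higher list, and the salt-inducible kinase gene Sik1, the endothelial tight junction gene Cldn5 and the homeobox gene Meis2 in the lower list. The regions were short. Their median width was 404 bp (95% interval of the median 398 to 409) in the higher list and 357 bp (352 to 364) in the lower list, and together they covered 1514 kb and 746 kb.

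Arid1a itself had no region in either list, and neither had Cx3cr1, Prg2 or Lrp6. The lists therefore offer no check of the knockout. Prg3, which encodes an eosinophil granule protein, had 1 region in the higher list, on chromosome 2 from 84984585 to 84985347, in the promoter class, between 2 and 3 kb upstream of the transcription start. These genes were chosen from knowledge of the study, so the Prg3 region is not independent evidence of a direction. Its score, 1.69, was below the lower quartile of the higher list, 1.95. Coordinates are those of the authors' lists, read as the GRCm38 mouse assembly because the transcripts given with the regions matched its genes.

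Among regions nearest to a gene with a name, the highest authors' score in the higher list, 90.8, belonged to a region on chromosome 19 from 58113288 to 58113596, nearest to Mir5623 and inside intron 28 of Atrnl1. Next came an intron of Cldn34d on chromosome X from 76598607 to 76599135, with a score of 42.1. Intergenic regions near the vomeronasal genes Vmn1r-ps2 and Vmn2r125, both on chromosome 4, scored 26.9 and 17.6. Gtpbp4 scored 22.9, Fanca 12.9, Rfesd 11.8 and the casein gene Csn1s1 11.3, with Kctd16 ranked between Gtpbp4 and Vmn2r125. The Gtpbp4, Fanca and Rfesd regions lay in introns of other genes, Gm36264, Gm20388 and Spata9. The neuronal splicing regulator Rbfox1 had 4 higher regions, all in its introns, and 2 lower regions, while Kctd16, Btbd3 and Pde4d had 3 each. Regions nearest to predicted genes scored far above these, up to 4950 at Gm10800 on chromosome 2 from 98666554 to 98667310 and 2786 at Gm10718 on chromosome 9 from 3023443 to 3024664. Whether such scores come from repeated sequence was not analysed.

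In the lower list, Sik1 had the highest score among genes with a name, 12.4, below 27.5 at the predicted gene Gm5626. Its region lay on chromosome 17 from 31854598 to 31854930, in the promoter, 862 bp from the transcription start. Introns of the bone matrix gene Mepe (12.4), Zfyve26 and the mitochondrial carrier gene Slc25a12 also ranked among the highest. Cldn5 had an intergenic region of score 11.7 on chromosome 16 from 18758710 to 18759132, upstream of its start. Zfp763 had an intronic region (10.6), Fhl2 a promoter region (10.5) and Mdga1 a 3' UTR region (9.40). The region nearest to Fam151b (10.3) lay in an intron of Zfyve16. Meis2 had a region over its transcription start on chromosome 2 from 116064340 to 116064761, with a score of 9.95. Nwd2 and Wdr72 had 3 lower regions each, and Sik1 and Cldn5 had 2 each.

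No fold change was given, so the size of the change could not be described. The authors' peak score, whose scale is not stated, is described in its place. The median score was 2.52 (2.52 to 2.69) in the higher list and 2.66 (2.57 to 2.66) in the lower list. The quartiles were 1.95 and 3.69 in the higher list and 2.19 and 3.61 in the lower list. The highest score was 4950 in the higher and 27.5 in the lower list. Scores served to rank regions within a list and cannot be read as the size of the change, and the lists may not share a scale.

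**Figure D1:**
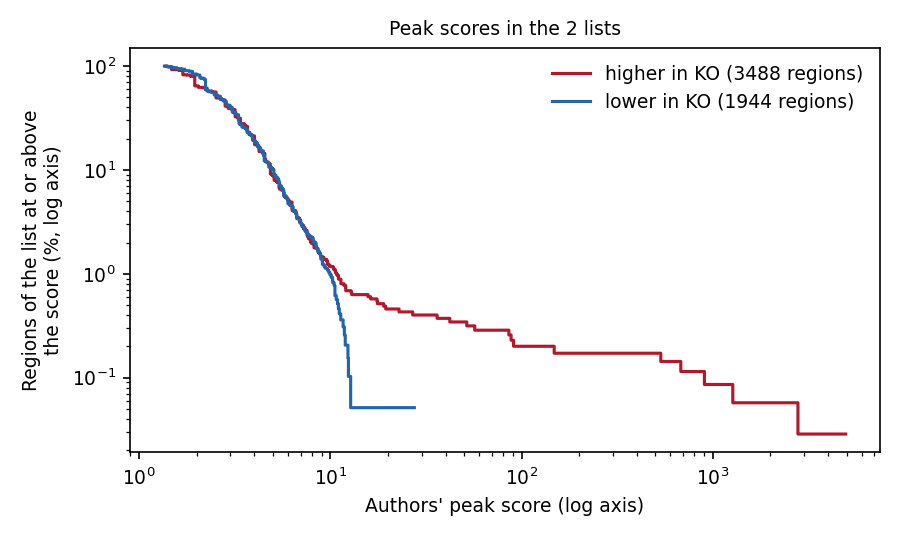
Share of each list (vertical log axis, percent of its regions) at or above each of the authors' peak scores (horizontal log axis). The medians were 2.52 in the higher and 2.66 in the lower list, and 7 regions of the higher list scored over 100.

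The position of the regions relative to genes was alike in both lists. Distal intergenic regions made up 47.9% (46.2 to 49.6) of the higher and 46.5% (44.3 to 48.7) of the lower list. Introns held 35.5% (33.9 to 37.1) and 36.4% (34.3 to 38.6), and promoters, within 3 kb of a transcription start, 12.6% (11.5 to 13.7) and 12.8% (11.4 to 14.4). Exons held 81 regions (2.32%) and 36 regions (1.85%), and the stretch downstream of genes 1.18% (0.845 to 1.59) and 1.13% (0.711 to 1.71). Untranslated regions were the classes that stood apart. The 3' UTR class held 19 higher and 20 lower regions, or 0.545% (0.328 to 0.849) and 1.03% (0.630 to 1.58). The higher share lay at percentile 2.33 of 10000 draws of as many regions from both lists. The 5' UTR class held 1 higher region, near Gm8565, and 5 lower regions, near Samd7, the myeloid tyrosine kinase gene Fgr, Prickle2, Kdm8 and Golm1. The higher share lay at percentile 1.28. These 5' UTR genes were named after their values were seen. Both classes hold few regions, and the percentiles were not corrected for the number of classes examined.

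Chromosome X differed from the autosomes. Of its 168 regions, 134 were higher and 34 lower, a share higher of 79.8% (72.9 to 85.6) against 63.8% (62.4 to 65.1) on the autosomes, and none of the 10000 draws reached a larger share. X regions in the higher list included some in introns of Cldn34d and the glutamate receptor gene Gria3. Others were distal intergenic, with the haem synthesis gene Alas2 or the neuronal migration gene Dcx as the nearest start. A promoter region of Pcdh19 was in the lower list. Single autosomes ranged from 59.5% on chromosome 19 (50.4 to 68.2) to 69.7% on chromosome 13 (63.5 to 75.5). Relative to the span of its genes, X held fewer regions than the genome in both lists, 0.610 (0.512 to 0.720) of the expected number in the higher and 0.278 (0.193 to 0.387) in the lower list. Chromosome Y had 7 higher and 8 lower regions, a share of 46.7% (21.3 to 73.4). The labels do not give the sex of the embryos.

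**Figure D2:**
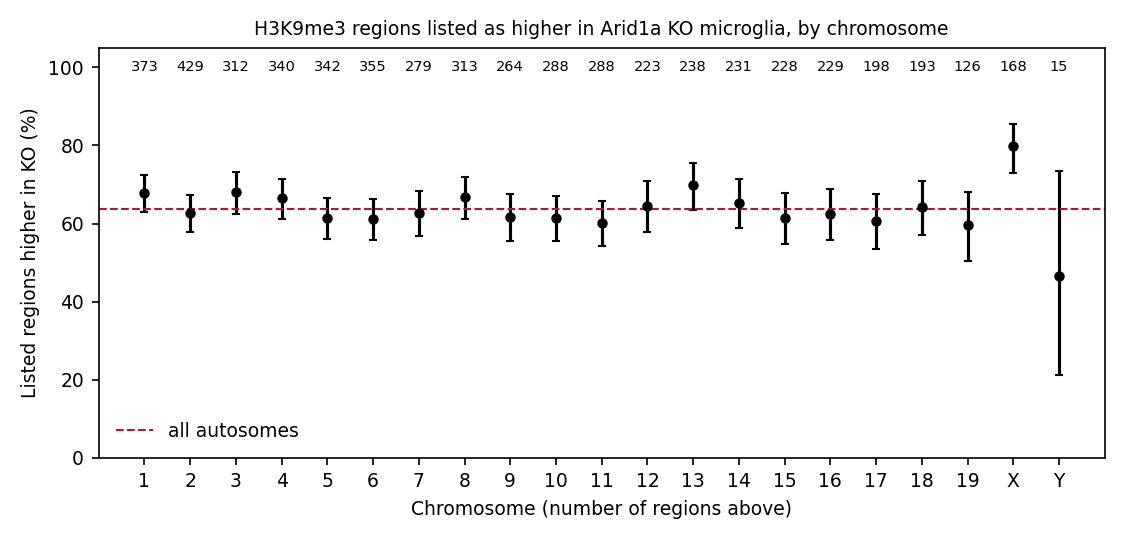
Share of the listed regions of each chromosome that were in the higher list (vertical axis, percent), with exact 95% binomial intervals as bars and the number of regions above. The dashed line is the autosomal share, 63.8%, and X lies above it at 79.8%.

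Genes of microglia and other myeloid cells had regions in both lists. Of 39 genes of homeostatic microglia, 3 had regions, all in the higher list. With only 4 regions the set had no percentile, so this one-sided count was not set beside random sets. Among them was the membrane-shaping gene Bin1, nearest to 2 regions with a highest score of 4.12, both in introns outside Bin1. A higher region of score 6.31 also lay in an exon of Csf1r, the receptor that microglia need to survive, although another gene's start was nearer. Of 42 genes of activated microglia, 4 had higher and 2 had lower regions, at percentile 56.9 of random sets of as many regions. By nearest start, the chemokine gene Cxcl10 (6.30), the cytokine gene Il1a (2.82), Spp1 and Lpl were in the higher list. The chemokine gene Ccl2 and the mannose receptor gene Mrc1 (2.47) were in the lower list. The Spp1 and Lpl regions were distal intergenic, and the Ccl2 and Mrc1 regions lay in introns of other genes. By the gene that holds the region, this set had 0 higher regions and 1 lower region, in an intron of Cd86 (1.90). Among 25 genes of border macrophages and blood myeloid cells, Mpo, the neutrophil myeloperoxidase (8.70), Stab1 and Prg3 were higher and Mrc1 lower.

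Genes of other cell types that a sort could carry over had regions in both lists by nearest start. Neural progenitor and neuron genes had 4 higher and 3 lower regions (percentile 38.5). Emx1, Neurod6, Slc1a3 and Dcx were in the higher list, and Neurod2 (3.07) and Rbfox3 (3.61) in the lower list. Vascular and erythroid genes had 4 higher and 5 lower regions (percentile 16.4). Dcn (5.70), Acta2 (4.85), Alas2 and Rgs5 were in the higher list, and Cldn5, Abcc9, Lum and the embryonic globin gene Hba-x in the lower list. By the gene that holds the region, the neural set had 3 higher and 3 lower regions and the vascular and erythroid set 3 higher, in Rgs5, Flt1 and Dcn, and 0 lower.

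Chromatin regulators had few regions by nearest start and more by the gene that holds the region. None of the 32 SWI/SNF genes had the nearest start to a listed region, although a higher region of score 2.52 lay in an intron of Arid1b, which encodes the paralogue of Arid1a. Of 47 genes of H3K9 methylation and its readers, Cbx5, which encodes the heterochromatin protein HP1 alpha, had 1 region, in its promoter and in the lower list (2.08). By the gene that holds the region, this set had 4 higher and 2 lower regions. Prdm16 held 2 higher and 1 lower, the histone demethylase genes Phf2 and Kdm3b 1 higher each, and Mecom 1 lower, all in introns.

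Wnt pathway genes had 6 higher and 3 lower regions by nearest start (percentile 50.7), and 6 higher and 0 lower regions by the gene that holds the region (percentile 95.7), in Tcf7l2, Ror1, Fzd3, Lrp5 and Lgr6. By nearest start, Wls (5.21), which encodes the carrier that Wnt proteins need for secretion, Lef1 (2.82), Lgr6, Fzd10, Wnt5b and Tcf7l2 were in the higher list. The Wnt inhibitor gene Dkk1 (4.16), Axin2 (2.47) and Tcf7l1 (2.22) were in the lower list. Neuronal gene sets were split as well. Axon guidance genes had 8 higher and 9 lower regions (percentile 3.55). The percentile was 1.42 for regions inside the gene or promoter and 28.3 by the gene that holds the region, with 14 higher and 9 lower regions. Lower regions lay at Dcc (7.36), Slit1 (3.92) and Gap43 (3.91), and a higher region at Sema6a (5.70). Dcc and Gap43 also had higher regions. Synaptic adhesion genes had 22 higher and 15 lower regions (41.2), led by Tenm2 (5.97) and Magi1 (5.73) in the higher and Dab1 (5.02) and Csmd2 (4.87) in the lower list. Ion channel and neurotransmitter receptor genes had 15 and 9 (42.4), with Kcnt2 (8.90) and Grin2a (4.32) lower and Kcnma1 (5.08) and Grik1 (4.59) higher. Autism-associated genes had 11 and 9 (13.4), with Setd5 (4.52) and Ank3 (4.02) higher, Pcdh19 (4.22) lower and Rbfox1 in both lists. By the gene that holds the region, autism-associated genes had 34 and 16 (64.3). Counted that way, synaptic adhesion genes had 58 and 33 (66.4), and ion channel and receptor genes 33 and 14 (76.8). By nearest start, imprinted genes had 4 and 1 (75.2), with Slc38a4 (4.01), Cdkn1c and Rasgrf1 higher and Kcnq1 lower. By the gene that holds the region they had 0 higher and 2 lower, in Usp29 and Trappc9.

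H3K9me3 is known from clustered gene families. The families below were chosen by symbol, whether clustered or not, and those with most regions had some in both lists. Zinc finger genes had 20 higher and 10 lower regions (percentile 48.3). Zfp763 (10.6), Zbtb7c (8.05), Zfp750 (5.99) and Zfp14 (4.16) were in the lower list and Zfp804b (4.12) in the higher list. Zfp750 also had a higher region (2.17). Olfactory receptor genes had 23 and 13 (42.0), with Olfr533 (6.31) and Olfr95 (4.23) higher and Olfr1183 (5.08) and Olfr717-ps1 (4.32) lower. Vomeronasal receptor genes had 14 and 4 (86.1), with Vmn2r-ps61 (5.39) higher and Vmn2r100 (6.13) lower beside the genes given above. Immunoglobulin and T cell receptor segments had 7 and 2 (78.9), led by Ighv13-1 (4.47) in the lower and Trav13d-4 (2.82) in the higher list. Keratin genes had 6 and 1 (83.7), the latter at Krt222. Serpin genes had 3 and 5 (3.43), with Serpinb13 (5.73) and Serpina3i (5.08) higher and Serpina1a (5.06) and Serpine2 (3.91) lower. Cytochrome P450 genes had 8 and 7 (15.4), led by Cyp1b1 (5.99) in the lower list. Cadherin and protocadherin genes outside the clusters had 3 and 3 (25.0), led by Cdh16 (6.54) in the lower list, and Pcdhgc3 (3.69) of the protocadherin clusters had 1 higher region. Solute carrier genes had 29 and 22 (13.5), led by Slc25a12 in the lower and Slc17a6 (9.66) in the higher list. MicroRNA genes had 42 and 27 (22.7), led by Mir5623 and Mir6349 (8.93) in the higher list. The defensin genes Defb4 (3.31), Defb7 (2.86) and Defb19 (2.22) each had a lower region in the promoter, the urinary protein gene Mup17 (2.47) and Snora26 (3.07) a lower region and Snord66 (3.57) a higher one. Histone genes had none.

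A set of testis and X-linked germ cell families stood apart, with 10 higher and 0 lower regions (percentile 99.1). Its best-scoring members were Tex22, Tex15 (9.84) and Tex26 (7.24), testis-expressed genes on autosomes, and Rhox7-ps2 (5.57) on X. Of the 10 regions, 2 belonged to Slx4ip, which is named for its partner in DNA repair and entered by its symbol, and without it the percentile was 97.8. Spin2-ps1, Tex13c3, Rhox7-ps2 and Rhox5 lie on X, where the share higher was larger, and with random sets also matched on X the percentile was 98.0. Counted only over regions inside the gene or its promoter, the set lay inside the random range, at percentile 93.3. Predicted genes, those named with Gm numbers, stood apart too, with 1798 higher and 941 lower regions, 65.6% higher (63.8 to 67.4, percentile 98.2). With each gene counted once their percentile was 97.3, inside the range, and by the gene that holds the region it was 29.2. RIKEN clone genes had 264 and 127 regions (percentile 89.6, and 100.0 by the gene that holds the region). Of the 32 sets, 22 had at least 5 regions by nearest start and so a percentile. Of these, 2 lay above the central 95% of random sets and 0 below it. By the gene that holds the region, 13 sets had a percentile, of which 1 lay above and 0 below. Chance would give 1.1 and 0.65 if every set could lie on both sides. The smallest sets could not lie above. Wnt genes by the gene that holds the region, with 6 higher and 0 lower, reached only 95.7.

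Regions in opposite lists shared genes about as often as chance assignment would give. Of 575 genes with at least 2 regions, 293 were in both lists, against 288 (central 95% of shuffles 266 to 311) when directions were shuffled over the regions. Rbfox1, with 4 higher and 2 lower regions, Rora, with 3 and 2, and Magi2, with 2 and 2, were examples. Directions of neighbours were not aligned either. Of the 1945 regions with a neighbour within 100 kb, 54.2% had a nearest neighbour of the same direction, against 53.9% (50.8 to 56.9) with shuffled directions.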

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

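The alternatives by median score, by the gene that holds the region, without the highest-scoring regions, with matching on X, without Slx4ip and by gene body were chosen after seeing the data. Of 149 alternative values for 39 results, 133 stayed on their side of the random range, inside the interval or near the count first found. Among them were 99 percentiles of gene sets, of which 16, in 10 sets, crossed the middle, such as synaptic adhesion genes (85.0 inside the gene or promoter) and RIKEN clones (47.8 above the median score). With a score at least 1 above the smallest, 2011 higher and 1103 lower regions were left. Within 10 kb of a transcription start lay 31.5% of the higher and 33.5% of the lower regions, a wider class than the promoter. At or above the median score of each list, the autosomal share higher was 66.0% and 101 genes were in both lists, against 94.6 (81 to 108) with shuffled directions. Axon guidance genes moved below the random range, to percentile 1.42 for regions inside the gene or promoter and 1.09 above the median score, but lay at 7.48 without width matching and 28.3 by the gene that holds the region. Predicted genes moved inside it, to 97.3 with each gene counted once, 96.9 with matching on X and 93.4 above the median score, and to the other side of the middle, 29.2, by the gene that holds the region. RIKEN clones moved above it, to 100.0, by the gene that holds the region. The testis and X-linked set moved inside it, to 93.3 inside the gene or promoter and 95.3 above the median score. Of neighbours within 10 kb, 48.2% had the same direction, against 54.0% (45.3 to 62.9) when shuffled. The cause was not tested, except that stricter scores and closer neighbours leave fewer regions. The planned stricter log2 change and p-value were not run because the lists hold neither, and the score stood in for them. The median level was replaced by the median width. No replicate could be left out. No paired analysis was possible because each group has 1 library. Unknown depth limits every count, since it sets which regions could be called.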

Other observations

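All tests in this part were chosen after the results were seen, including the limits that decide them, and the random placement is among them. Long noncoding RNA genes held 354 regions of the higher list, above the 310 (278 to 345) of random placements, and 193 of the lower list, inside the range of 150 to 200. Protein-coding genes held 1349 higher regions, below the 1420 (1365 to 1474) of random placements, and 824 lower regions, inside it. RIKEN clone genes had 179 higher regions within 10 kb against 134 (112 to 157). Serpin genes, such as Serpina1a and Serpine2, had 6 lower regions against a random range of 0 to 4, and vomeronasal receptor genes 3 lower regions against 12.7 (6 to 20). Over gene bodies without flanks the serpin count stayed above its range, 0 to 3, while the vomeronasal count, 2, lay inside 1 to 9. Without flanks, the testis and X-linked set, with 7 higher regions against 2.94 (0 to 6), and the defensin genes, with 3 lower regions against 0.255 (0 to 2), lay above theirs. The count of the testis and X-linked set was not repeated without Slx4ip, which entered by its symbol. Homeostatic microglia genes had 6 higher regions within 10 kb against 2.69 (0 to 6) and 1 lower region against 1.46 (0 to 4), both inside the range. By the gene that holds the region, the genes with most regions included the neuronal adhesion gene Lsamp, with 6 higher and 2 lower, Opcml, with 5 and 2, Galntl6, with 5 and 0, and the common fragile site genes Fhit and Wwox, with 4 and 1 and with 4 and 2. Protein-coding genes of 200 kb or more together held regions at the random rate, 605 higher against 575 (536 to 619) and 329 lower against 322 (292 to 354).

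Some of the highest scores of the higher list sat together. Of its 14 regions with the highest scores, a number set by the top score of the lower list although the lists may not share a scale, 6 (42.9%) lay on chromosome 9 between 3000294 and 3035275, at Gm10722, Gm11168, Gm26870, Gm10718, Gm10717 and Gm17535. The other 8 each lay alone, and included Gm10800 on chromosome 2 (4950), Gm33838 on chromosome 9 (903), Gm21738 on chromosome 14 (680) and Gm21379 on chromosome Y (36.2). Repeats and mappability were not analysed, so these scores cannot be read as gains of H3K9me3 at the genes named.

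Regions on X were in the higher list more often than autosomal regions. A trend with gene density that also holds on autosomes would put X inside the range of autosomal sets matched on gene density, which ended at 71.4%, although gene-poor autosomal windows did have more higher regions (67.4%) than gene-rich ones (59.9%). More female embryos in the KO pool could also raise X, and the Y share of 46.7% over 15 regions is too imprecise to decide. A difference in depth that lets more regions of a single-copy X pass a threshold, and an effect of Arid1a loss on X, stay open and untested.

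Scores in the lists took nearly separate values. Of 4804 regions whose score value occurred at least 10 times, 99.3% had a value found at least 95% in 1 list, against at most 0.791% in 1000 shuffles. The commonest higher value was shared by 534 higher regions and 0 lower ones. Why the values differ was not tested. The choice of named genes within a set and the stricter score applied 1 scale to both lists, which these values put in doubt.

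The listed regions lay near most gene sets about as often as random positions on the same chromosomes. Of 64 combinations of a list with a gene set, 3 lay outside the central range of random placements, and 4 did so for gene bodies alone. Chance would give 3.20 if every combination could lie on both sides, but sets whose random range starts at 0 cannot lie below it. The protein-coding and noncoding classes given above are not among the 64. Positions drawn evenly along all chromosomes would put the X density in the lower list at that of the genome, and it was 0.278 of it, and 0.610 in the higher list, with chromosome length taken as the span of its genes. The prediction holds only if X was present in as many copies as the autosomes. The sex of the embryos is not given, so the low X density cannot decide whether positions were drawn evenly. Even scatter along the autosomes was not settled: 2.41% of higher regions lay within 10 kb of another against 2.80% (2.06 to 3.61) at random, but densities ran from 0.840 to 1.32, with chromosome 11 at 1.32 (1.10 to 1.58) in the lower and chromosome 8 at 1.26 (1.10 to 1.44) in the higher list, and the low X and Y raise these ratios. A difference seated at zinc finger genes would put more regions within 10 kb of them than random placement. Both lists together had 0.735 of the random mean, a ratio without a range of its own. Each list lay inside its range (28 in 24 to 46 and 12 in 12 to 28). The genes were chosen by symbol, whether clustered or not, so zinc finger clusters were not tested by themselves. Repeats and mappability were not analysed here, and an effect of Arid1a loss at single genes stays open.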
